A study of Fusarium verticillioides with 12 samples.

How the data were processed

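Poly(A) RNA of *Fusarium verticillioides* colony edges was measured in 12 samples, 3 in each of 4 groups: control, fengycin, surfactin and the combined treatment. Per the labels' protocols, poly(A) RNA was selected with poly-T beads and libraries were made with a TruSeq kit. Per the submitters' processing notes, TopHat2 2.0.14, Cufflinks 2.21 and Cuffdiff 2.2.1.3 were used. Aligner options, library scaling, strand setting, treatment of reads with several alignments and the name of the genome build are not given in the sources used here.

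The authors' deposited table is in the layout of a Cuffdiff gene table, with 17169 loci in each of 6 pairwise comparisons. Its FPKM values, as deposited, are fragments per kilobase, scaled to the mapped fragments, 1 value per group and locus. Its score is the deposited Cuffdiff test statistic, and its p-value and q-value are as the authors deposited them, with a smallest p of 5e-05. The table label "Double" was taken as the combined treatment, the remaining group of the labels. The table held no values per sample, so no depth per sample, leave-one-out value or refit of a model could be had. Of all FPKM values, 14.7% were 0, and no fold is given against a group at 0. The deposited column of log2 fold changes held spreadsheet errors, so log2 fold changes were recomputed from the FPKM values.

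Locus tags were looked up in a gene table of assembly ASM14955v1, where 16203 of 16203 tags matched. All 14815 loci with a single gene contained that gene's reference coordinates. Starts are given counted from 1. The gene table named no products, and its nuclear symbols were the locus tags. Of 23 gene lists fixed before the data were examined, 0 could be filled, and the gene list tests were not run. Loci were classed as protein-coding, protein-coding and overlapping an rRNA gene, rRNA, tRNA or without an annotated gene.

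The 6 pairwise comparisons, the tests, the threshold, the rule for named genes and most alternatives were set before the data were examined. A locus was called when its status was OK and its deposited q was 0.05 or less, adjusted by Cuffdiff. The rule named, for each comparison with control, the 2 highest and 2 lowest log2 fold changes among called loci with FPKM above 0 in both groups and the larger at least 5. Parts of the rule that needed annotated products or gene lists could not be applied. Genes outside the rule were chosen after their values were seen.

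The standard error of each log2 fold change was taken as the change divided by the deposited test statistic. For 12240 loci with all 6 tests and all FPKM above 0, the 4 group variances were solved from the 6 standard errors by least squares, and the median largest error was 0.0015%. The square root of a group's variance is called its implied error. Its median on the log2 scale was 0.23 in control, 0.35 in fengycin, 0.22 in surfactin and 0.25 in the combined group. It was used as a standard error, and the alternative that divides the variance by 3 reads it as an SD of 3 samples. Departure from additivity, and the main effects averaged over the other lipopeptide, were tested with z tests and Benjamini-Hochberg adjustment. At most loci the deposited p-values were smaller than a normal reading of the same statistics, as at 97.0% of 12991 loci for fengycin against control. At a statistic near 2, the median deposited p for fengycin against control was 0.0018, and the normal two-sided p is 0.0455. The gap was not alike in all comparisons: the median deposited p was 0.00073 for the combined treatment against surfactin and 0.0313 for it against fengycin. Some large statistics went the other way: of loci with a statistic of at least 3 in size, 46 of 152 for fengycin against control and 59 of 93 for the combined treatment against fengycin had a deposited p above 0.05. The source of this gap is not given in the sources used here, so the SEs and the deposited p-values do not measure the same spread.

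Correlations of fold changes were set beside 100 simulations of unchanged groups against the same control. Overlaps of calls were set beside the same simulations and the overlap of independent lists. Enrichment of calls by class of locus used two-sided Fisher's exact tests, adjusted over 30 tests. Neighbouring calls, windows of 8 loci and loci within 300 kb of chromosome ends were tested with 1000 permutations of calls within FPKM deciles, and were added after the data were examined.

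Computation used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. On simulated data over 8434 loci, the additivity test recovered 4% of 50 loci with a planted log2 departure of 1, 60% of 50 at 2, 90% of 50 at 4 and 96% of 50 at 6. It called 0.085% of 8234 unchanged loci. The simulated noise was drawn from the same variances that the test then used. These shares therefore do not allow for error in the variances, and the rate of false calls in the data was not measured. The window search, simulated for the 12301 loci of fengycin against control, found the planted region in 10 of 10 draws and a region among random calls in 0 of 10.

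Alternatives were a stricter q, a 2-fold minimum, FPKM minimums of 1 and 5, adjustment within a comparison, normal p-values from the statistic, leaving out loci at 0, recentred folds, a pseudocount of 1 FPKM, Spearman's rho and other definitions of additivity. Restriction to protein-coding loci and division of the variance by 3 were chosen after seeing the data.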

Results

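Poly(A) RNA was sequenced from colony edges of *Fusarium verticillioides*, a filamentous fungus that infects maize and makes fumonisin mycotoxins. Colonies of strain FRC-M3125 had grown for 5 days in the dark at 27 °C on potato dextrose agar. Their edges then received 100 µL of 0.2X potato dextrose broth with fengycin, surfactin, both lipopeptides together (the combined treatment) or neither (the control), and were harvested 6 h later. Fengycin and surfactin are cyclic lipopeptides that *Bacillus* species secrete, here named in the labels as those of *Bacillus mojavensis*. Each joins a peptide ring to a fatty acid chain, and the peptide of fengycin is the longer. The labels gave no dose for either compound. There were 12 samples, 3 in each of 4 groups. The authors' deposited table held 1 FPKM value per group for 17169 loci and no value per sample, so the depth of each sample is unknown. Errors are standard errors of the log2 fold change implied by the deposited test statistics. The labels do not say whether the 3 samples of a group came from separate cultures, so the spread between these samples may be technical. The deposited p-values and the implied errors did not measure the same spread, and which spread the p-values measure is not known.

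Genes carry only their FVEG locus tags, since neither the table nor the reference gene list gave names or products. Positions refer to assembly ASM14955v1. Of the 17169 loci, 15244 held protein-coding genes with no rRNA gene inside, 34 held protein-coding genes that overlapped an rRNA gene, 66 were rRNA loci, 268 were tRNA loci and 1557 had no annotated gene. "Higher" and "lower" are used of loci called at the deposited q of 0.05 or less.

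**Figure D1:**
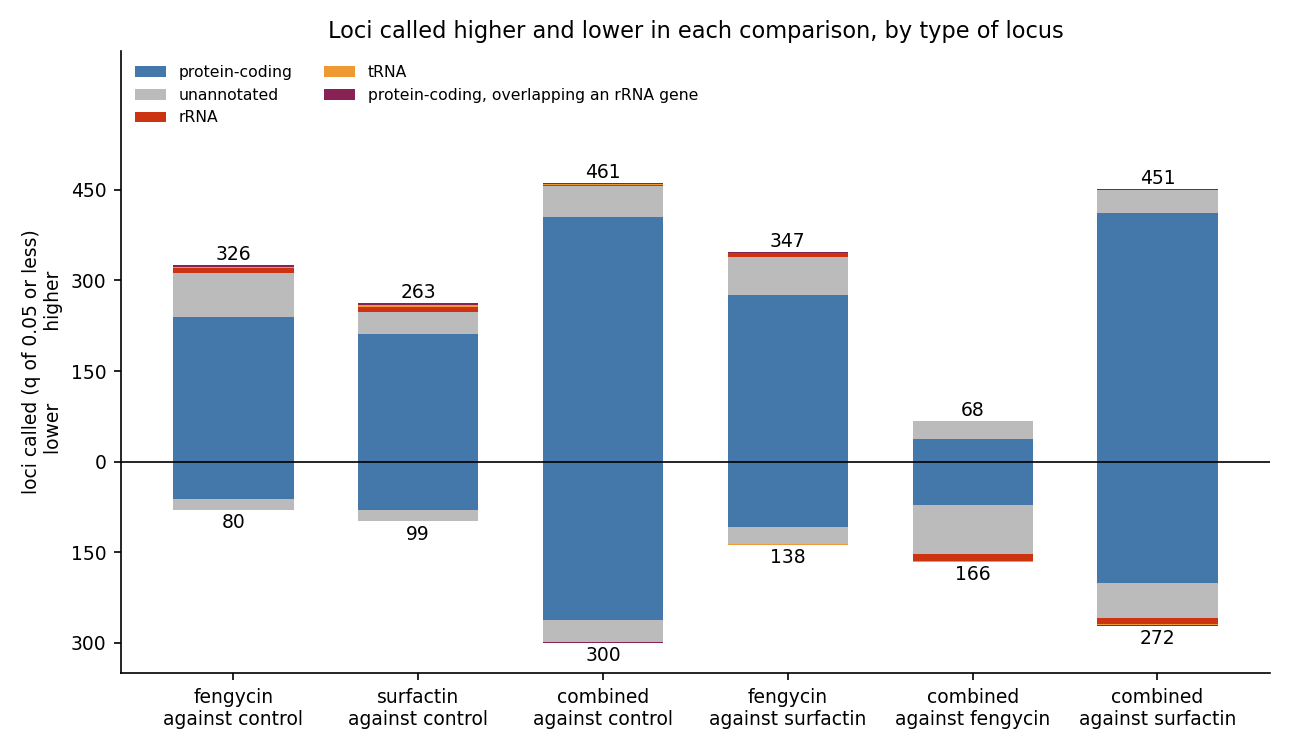
Number of loci called in each of the 6 comparisons (horizontal axis), with loci higher in the group named before "against" drawn upward and lower loci drawn downward, coloured by type of locus. The combined treatment was called against control at 461 higher and 300 lower loci, while it was called against fengycin at 68 higher and 166 lower loci.

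The comparison of fengycin with control asks which genes respond to fengycin alone. Most loci called with fengycin were higher: 240 protein-coding loci in the authors' deposited table were higher and 61 lower among 12301 tested. Most loci were not called, and over tested protein-coding loci with a larger FPKM of at least 5 the median log2 change was -0.07. Among called loci with FPKM above 0 in both groups, the median change was 2.30-fold for the 217 higher loci and 1.66-fold for the 52 lower ones. FVEG_12284 on chromosome 4 (3595850 to 3596559) rose from 45.2 to 667 FPKM in the authors' deposited table, a log2 fold change of 3.88 (SE 0.31, Cuffdiff q = 0.00258). FVEG_05378 on chromosome 3 (3431772 to 3432595) rose from 2.11 to 32.0 FPKM in the same way (log2 3.92, SE 0.68), again from the authors' deposited table. Among 7 neighbouring loci on chromosome 8 (506462 to 532233, FVEG_07592 to FVEG_07584), 4 were higher, and the median log2 change was 0.81.

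The fixed rule for named genes took the extremes of the fengycin comparison, and its highest genes both overlapped rRNA genes. FVEG_07879 on chromosome 3 (1141745 to 1146007) went from 4.75 to 1398 FPKM in the authors' deposited table (log2 8.20, SE 0.99, Cuffdiff q = 0.00258). FVEG_17540 on chromosome 8 (2687428 to 2690152) went from 17.2 to 3223 FPKM in the authors' deposited table (log2 7.55, SE 0.44). Reads of the rRNA gene and of the protein-coding gene cannot be told apart at such loci. Loci of rRNA genes themselves were called higher 7 times among 37 tested and lower 0 times. The lowest by the rule were the locus of FVEG_00599 and FVEG_14695 on chromosome 1 (4477890 to 4484265), at 26.9 FPKM in control and 4.38 in fengycin in the authors' deposited table (log2 -2.62, SE 0.87), and that of FVEG_11461 and FVEG_11462. The latter, on chromosome 7 (2208166 to 2211976), was at 122.7 and 13.8 FPKM in the authors' deposited table, and its log2 change of -3.15 was smaller than its implied SE of 3.97 although the deposited q was 0.0131. A normal p from the deposited test statistics, adjusted within the comparison, called 121 loci in place of 406.

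The comparison of surfactin with control asks the same of surfactin alone. Its changes were smaller: 212 protein-coding loci in the authors' deposited table were higher and 80 lower among 12248 tested. For loci above 0 in both groups the median change was 1.77-fold among the 200 higher and 1.59-fold among the 78 lower. These medians are of called loci, and the fold needed for a call grows with the spread of a group. Among 8434 protein-coding loci with a mean FPKM of at least 5, 115 changed at least 2-fold with surfactin and 271 with fengycin. The median absolute deviation of their log2 fold changes was 0.133 and 0.203. The fengycin group also had the larger median implied error, 0.35 against 0.22, so how far its effects are larger was not settled. On chromosome 11 (1362162 to 1374605) 4 of 5 tested loci rose, FVEG_10719, FVEG_10718, FVEG_10717 and FVEG_10716. FVEG_10716 went from 44.0 to 96.1 FPKM (log2 1.13, Cuffdiff q = 0.00258) in the authors' deposited table. On chromosome 3 (765649 to 809209, FVEG_12532 to FVEG_12519) 8 of 13 tested loci fell together and 0 rose. The median log2 change of these 13 loci was -0.54 with surfactin, 0.38 with fengycin and -0.18 with the combined treatment. Within this stretch FVEG_12529 was at 132.4 FPKM in control, 90.8 in surfactin, 231.0 in fengycin and 166.5 in the combined treatment in the authors' deposited table. These stretches and the others named by position were found after the data were examined, by a search over windows of 8 neighbouring loci, and their genes were chosen after their values were seen. Each stretch was cut to its first and last called locus, so uncalled loci beside it are left out of its counts and medians.

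**Figure D2:**
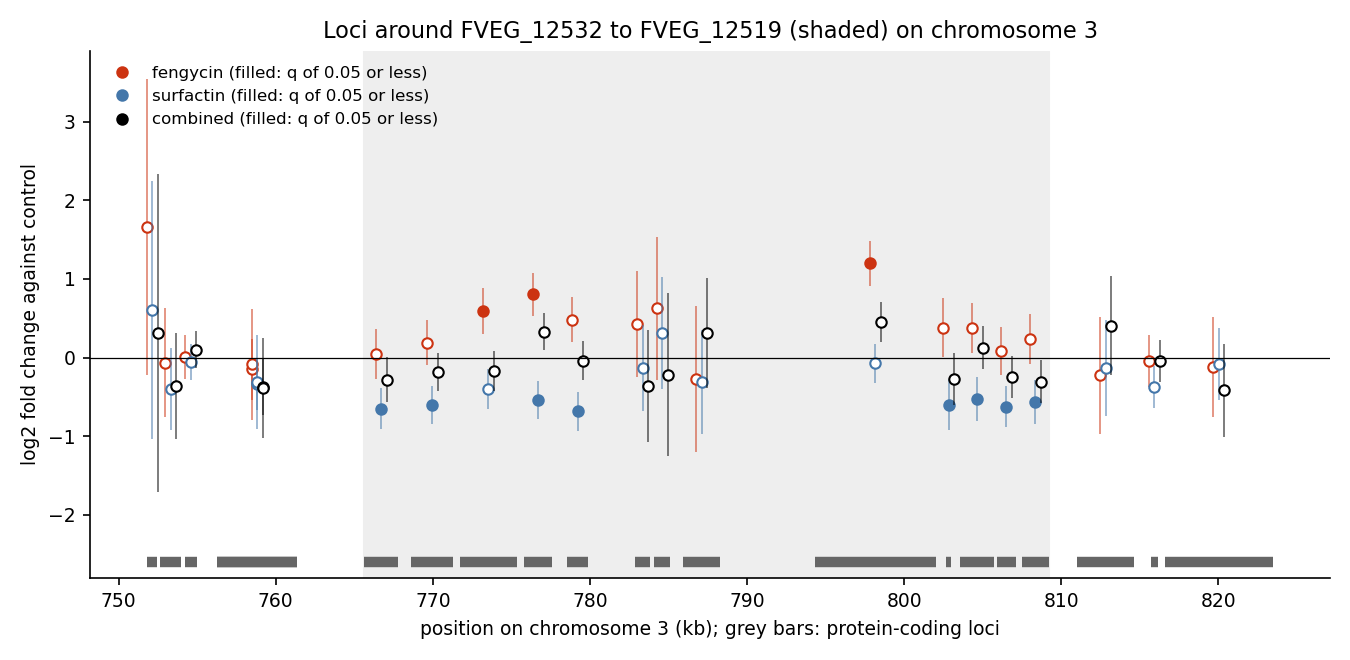
Log2 fold change against control (vertical axis) of protein-coding loci along part of chromosome 3 (horizontal axis, kb) for fengycin, surfactin and the combined treatment; filled points have a deposited q of 0.05 or less, and bars are the standard errors implied by the deposited test statistics. In the shaded stretch from FVEG_12532 to FVEG_12519, 8 of 13 loci were called lower with surfactin, and 3 were called higher with fengycin.

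By the fixed rule, surfactin's highest genes were again FVEG_07879 (554.9 FPKM) and FVEG_17540 (1780 FPKM) in the authors' deposited table, with log2 changes against control of 6.87 (SE 0.38) and 6.70 (SE 0.13). Loci of rRNA genes were called higher 9 times among 33 tested and lower 0 times. Its lowest were FVEG_17658 on chromosome 8 (1991970 to 1993676) and the locus of FVEG_11461 and FVEG_11462. FVEG_17658 was at 261.9 FPKM in control and 1.27 in surfactin in the authors' deposited table (log2 -7.68, SE 0.83, Cuffdiff q = 0.00258). The gene was also low in fengycin, at 0.473 FPKM, where the authors' deposited table gave a q of 0.640 and no call. The locus of FVEG_11461 and FVEG_11462 was at 11.3 FPKM in surfactin in the authors' deposited table (log2 -3.44, SE 0.26). Requiring at least a 2-fold change left 163 of the 362 called loci, and a normal p from the test statistics called 106.

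The combined treatment against control asks what both lipopeptides do together. More genes were called than for either lipopeptide alone: 405 protein-coding loci were higher and 262 lower among 12400 tested in the authors' deposited table. Its fold changes were no wider than those of fengycin. Among 8434 protein-coding loci with a mean FPKM of at least 5, 277 changed at least 2-fold with the combined treatment and 271 with fengycin, and the median absolute deviation of the log2 fold changes was 0.199 and 0.203. The median log2 error implied by the statistics was lower in the combined group (0.25) than in the fengycin group (0.35). FVEG_05378 rose to 49.1 FPKM (log2 4.54, SE 0.62) and FVEG_12284 to 673 FPKM (log2 3.89, SE 0.28), both with a Cuffdiff q of 0.00258 in the authors' deposited table. The lowest by the rule were FVEG_17658, at 0.556 FPKM (log2 -8.88, SE 2.10, Cuffdiff q = 0.00457), and the locus of FVEG_11461 and FVEG_11462, at 11.3 FPKM (log2 -3.45, SE 0.26), in the authors' deposited table. On chromosome 7 (163555 to 187946, FVEG_06552 to FVEG_15890) 5 of 8 tested loci were higher, among them FVEG_06554, which rose from 6.44 to 34.0 FPKM in the authors' deposited table. Only 1 of 30 tested rRNA loci was called higher. A normal p from the test statistics called 156 loci in place of 761, and requiring a 2-fold change left 387.

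Most genes raised by fengycin were raised by the combined treatment as well. Of the 227 protein-coding loci called higher with fengycin and tested in both comparisons, 173 were also higher with the combined treatment, against 7.27 for independent lists. Of 206 loci called higher with surfactin, 72 were higher with the combined treatment, against 6.50 for independent lists. Simulated groups without effects, set against the same control, shared at most 3 calls in either case, but they gave hardly any calls and so do not show what the control adds to lists this long. These comparisons share the control libraries, and part of the excess may come from them, since the control could not be split. Fengycin and surfactin shared 32 higher loci, against 3.59 for independent lists, and 9 lower loci, against 0.41. Another 3 loci were higher with fengycin and lower with surfactin, and 0 the other way.

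The log2 fold changes of fengycin and surfactin against their shared control correlated across 12240 loci at Pearson r = 0.453 (95% interval 0.439 to 0.467) and Spearman rho = 0.274, where genes are not independent replicates. Over the 8549 loci with a mean FPKM of at least 5 it was 0.570. Over the 8434 of them that were protein-coding and overlapped no rRNA gene, which leaves out rRNA, tRNA and unannotated loci together, it was 0.335. For these 8434 loci the covariance was 0.0535. Unchanged groups simulated with the variance implied by the test statistics gave a covariance of 0.165 and an r of 0.410, and with that variance divided by 3 they gave 0.0578 and 0.419. Over these loci the observed covariance did not exceed the share that the common control gives by either reckoning. Over the 8549 loci it was 0.150, below the simulated 0.177 but above the 0.0604 simulated with the variance divided by 3.

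Fengycin against surfactin compares the related lipopeptides directly at the same time after treatment, at doses the labels do not give. Of the protein-coding loci in the authors' deposited table, 275 were higher with fengycin and 108 higher with surfactin among 12328 tested. FVEG_12284 was at 667 FPKM with fengycin and 43.7 with surfactin in the authors' deposited table, close to its control level of 45.2 in the latter. FVEG_05378 was at 32.0 FPKM with fengycin and 1.17 with surfactin in the authors' deposited table. Genes higher with surfactin included FVEG_02442 on chromosome 6, at 51.4 against 8.81 FPKM, and FVEG_13208 on the same chromosome, at 31.0 against 5.78 FPKM in the authors' deposited table (both Cuffdiff q = 0.00258); these were chosen after their values were seen. In the stretch of chromosome 3 described above, 10 of 13 loci were higher with fengycin, with a median log2 difference of 0.80. Precision varied between loci, called or not: the 95% interval of the difference lay within 2-fold for 42.4% of the 8434 protein-coding loci with a mean FPKM of at least 5, and its median half-width was 0.82 on the log2 scale. A normal p from the test statistics called 137 loci in place of 485.

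**Figure D3:**
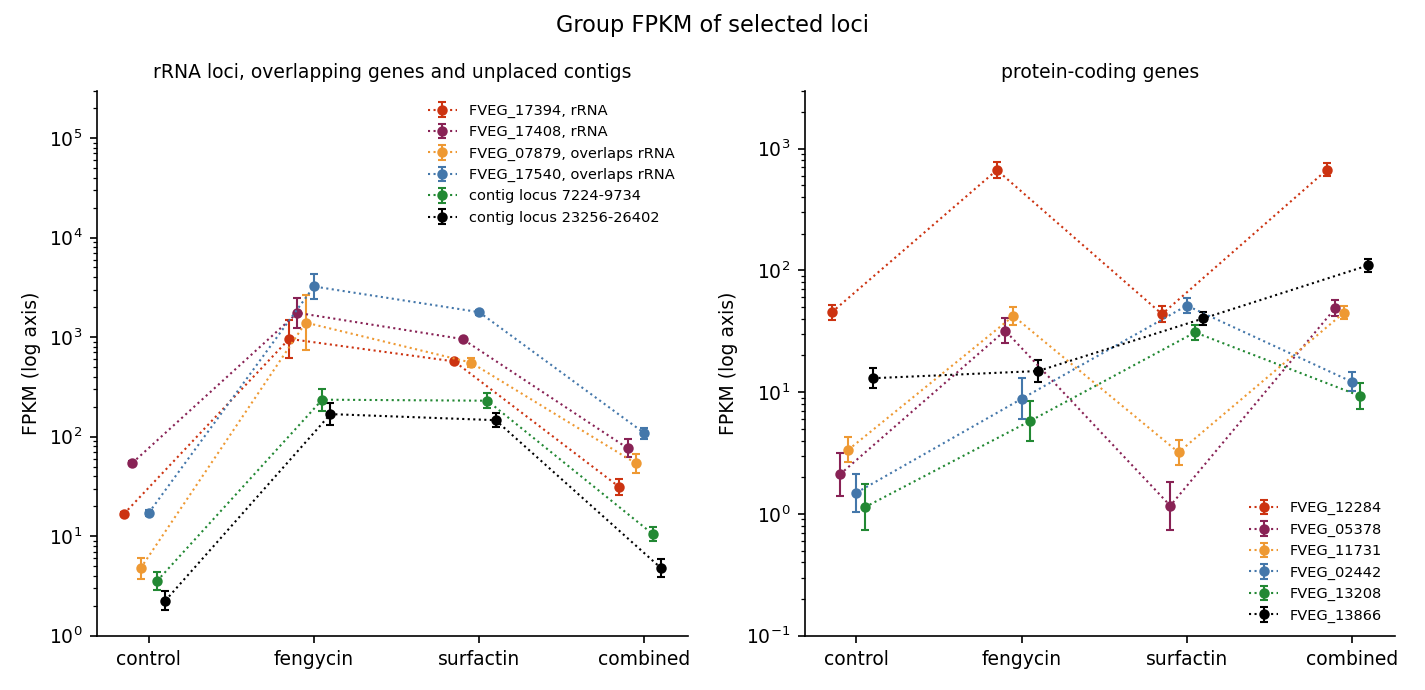
FPKM (vertical log axis) of selected loci in the 4 groups (horizontal axis), with rRNA loci, genes overlapping rRNA genes and unplaced contigs on the left and protein-coding genes on the right. Bars are the error per group implied by the deposited test statistics, and dotted lines join values of the same locus. Loci on the left are higher in fengycin and surfactin than in the other groups, whereas on the right FVEG_12284 is at 667 and 673 FPKM in fengycin and the combined treatment and at 45.2 and 43.7 FPKM in control and surfactin.

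Fewer genes were called between the combined treatment and fengycin than between it and surfactin. Against fengycin, 37 protein-coding loci were higher and 72 lower among 12383 tested in the authors' deposited table. Only 48 of these had FPKM above 0 in both groups, 23 of them higher and 25 lower. Against surfactin, 412 protein-coding loci were higher and 200 lower among 12382 tested in the authors' deposited table, and 556 of them had FPKM above 0 in both groups. FVEG_13866 on chromosome 8, chosen after its values were seen, was at 110.2 FPKM with the combined treatment, 14.9 with fengycin and 40.3 with surfactin in the authors' deposited table, with a Cuffdiff q of 0.00258 against fengycin and 0.299 against surfactin. On chromosome 8, 6 of 9 tested loci from FVEG_07586 to FVEG_07578 (527267 to 543548) were higher with the combined treatment than with surfactin. From FVEG_07746 to FVEG_07737 (92700 to 119972), 6 of 11 tested loci were lower. Loci of rRNA genes fell in both comparisons: 11 of 38 tested were lower than with fengycin and 10 of 35 lower than with surfactin, and 0 were higher. The contrast was smaller in the fold changes than in the calls. Across the 8434 protein-coding loci, 141 differed at least 2-fold from fengycin, 123 of them not called, and 233 from surfactin, 96 of them not called. The median absolute deviation of the log2 fold changes was 0.149 against fengycin and 0.201 against surfactin. In the authors' deposited table the median p at a test statistic near 2 was 0.0313 against fengycin (24 loci) and 0.00073 against surfactin (82 loci), so the same statistic was called less readily in the former. A normal p from the test statistics called 82 loci against fengycin in place of 234, and 194 against surfactin in place of 723.

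The fengycin effect could be compared without and with surfactin in groups that share no library. Across the 8434 protein-coding loci, fengycin against control and the combined treatment against surfactin correlated at r = 0.475 (95% interval 0.458 to 0.491; rho = 0.445). Surfactin against control and the combined treatment against fengycin correlated at r = 0.147 (95% interval 0.126 to 0.168; rho = 0.0911). Both values depended on the loci kept, a choice made after the data were examined. Over all 12240 loci the fengycin pair correlated at 0.131 (rho = 0.323) and the surfactin pair at -0.094 (rho = 0.0659). Over the 8549 loci with a mean FPKM of at least 5 they correlated at 0.0978 (rho = 0.426) and -0.245 (rho = 0.0762). The Pearson r of the surfactin pair thus changed sign with the loci kept, and these correlations are across loci, which are not independent replicates. Of 227 loci called higher with fengycin, 144 were also higher in the combined treatment than in surfactin, against 7.65 for independent lists, and 10 were lower there. Of 206 loci called higher with surfactin, 12 were higher in the combined treatment than in fengycin, against 0.45, and 5 were lower. Of the lower loci, 10 of 54 for fengycin were lower in both comparisons, against 0.84 for independent lists, and 4 of 79 for surfactin, against 0.30.

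**Figure D4:**
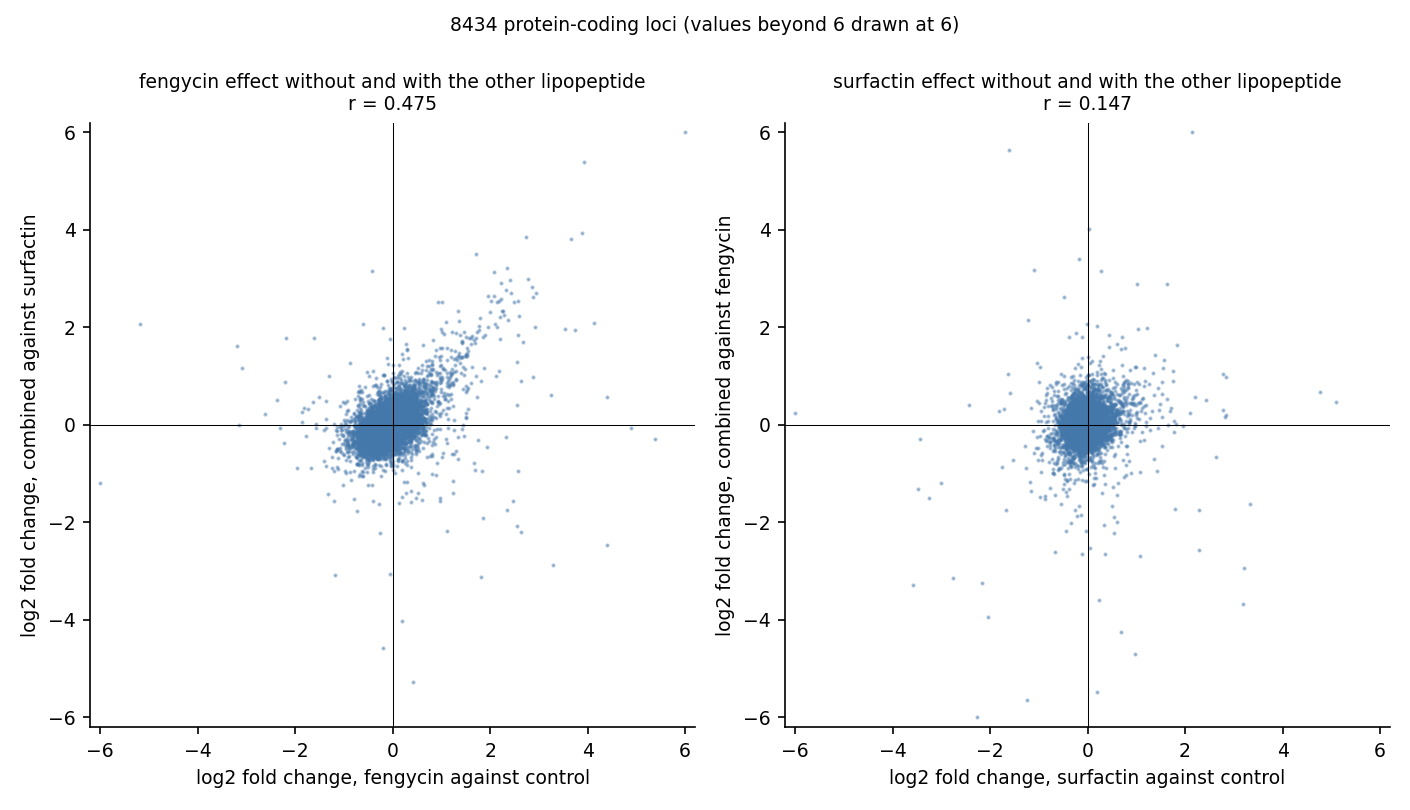
Log2 fold changes of 8434 protein-coding loci with a mean FPKM of at least 5, for the fengycin effect without surfactin (horizontal) and with it (vertical) on the left, and the surfactin effect without and with fengycin on the right; values beyond 6 are drawn at 6, and each point is a locus. The fengycin effects correlate at 0.475 and the surfactin effects at 0.147 over these loci, against 0.131 and -0.094 over all 12240 loci.

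Departures from additivity on the log2 scale asked whether the combined treatment equals the sum of both effects. Of 12240 loci with all tests and FPKM above 0, 36 departed at a Benjamini-Hochberg adjusted p of 0.05 or less in a z test, 35 below the sum and 1 above it. They comprised 15 rRNA loci, 2 tRNA loci, 8 without a gene, 3 protein-coding loci that overlapped rRNA genes and 8 other protein-coding loci. Some of these last 8 were also high in both single treatments. In control, fengycin, surfactin and the combined treatment, the locus of FVEG_02298 and FVEG_15015 was at 5.48, 116, 50.1 and 9.06 FPKM. That of FVEG_11511 and FVEG_11513 was at 20.7, 128, 100 and 21.8. A 47 bp locus without a gene departed by only -0.35, and its call rests on a very small implied SE of 0.0004. FVEG_02219 on chromosome 6 (1780576 to 1782319), likewise chosen after its values were seen, was at 323 FPKM with fengycin but at 7.71 in control, 8.86 with surfactin and 7.22 with the combined treatment in the authors' deposited table, a departure of -5.69 (SE 0.56). FVEG_02442 and FVEG_13208 rose most with surfactin alone and reached 12.2 and 9.29 FPKM in the combined treatment in the authors' deposited table, departures of -4.64 and -4.09. With the variance divided by 3, 104 loci departed, 84 below the sum and 20 above it. Because the labels do not state whether the combined treatment held each lipopeptide at its full dose, the sum of both effects is a reference point and no prediction.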

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

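All the tests of explanations in this part were chosen only after the result was seen, while the test of additivity was set before the data were examined.

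FVEG_02219 rose with fengycin alone and stayed near its control level in the combined treatment, where its log2 departure from the sum of the single effects was -5.69 (SE 0.56). FVEG_02442 and FVEG_13208 on chromosome 6 rose most with surfactin alone and departed by -4.64 (SE 0.83) and -4.09 (SE 0.92). These genes, chosen after their values were seen, differed in their fengycin effect with and without surfactin. The same test named 36 loci in all, 35 of them below the sum. The genes FVEG_07879 and FVEG_17540, which overlap rRNA genes, departed by -11.57 (SE 1.04) and -11.59 (SE 0.48). Another 16 loci, all of rRNA genes, lay outside the measurements because Cuffdiff held them too deep to quantify. This number held in comparisons with fengycin or surfactin, against 7 in the combined treatment against control.

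Most measured loci of rRNA genes, some genes overlapping them and several loci on unplaced contigs shared a shape. They were higher in both single treatments than in control and the combined treatment. The combined treatment was not always at the control level. Of 44 rRNA loci above 0 in some group, 24 were above control in the combined treatment, with a median FPKM of 13.4 against 0.416. Only 1 of 30 tested rRNA loci was called higher there. FVEG_07879, which overlaps an rRNA gene, was called higher at 53.8 against 4.75 FPKM (Cuffdiff q = 0.0131) in the authors' deposited table. The contig locus at 23256 to 26402 was at 2.25 FPKM in control, 168 in fengycin, 146 in surfactin and 4.80 in the combined treatment in the authors' deposited table. That locus was also called higher in the combined treatment than in control (Cuffdiff q = 0.00258). Among rRNA loci, 11 of 38 were lower in the combined treatment than in fengycin (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.47e-12), and 10 of 35 lower than in surfactin (adjusted p = 5.40e-09). Loci of rRNA genes are not independent replicates and may share reads with several alignments. These p-values therefore do not measure the spread between samples. Of 45 loci with at least a 4-fold form of this shape, 20 spanned more than 1 kb, 6 of them contig loci without a gene. The other long ones were rRNA loci or genes overlapping an rRNA gene. The span of a locus is not the length of the transcripts in it. Inflated FPKM at short transcripts within these loci therefore stays open. Among 44 rRNA loci above 0 in some group, 72.7% had a larger FPKM in both single treatments than in both other groups, whether called or not. The share was 9.69% of protein-coding loci and 32.3% of 31 protein-coding loci that overlapped an rRNA gene. The share at rRNA loci describes the pattern and decides nothing about its cause, since the pattern was first seen there. More rRNA carried through poly(A) selection in the fengycin and surfactin libraries, and a response of the fungus to each lipopeptide that the combination cancels in whole or in part, cannot be told apart. Of 18 rRNA loci with FPKM above 0 throughout, 15 departed from additivity, which a library difference between the same groups also gives.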

How the results depend on the processing

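Tests that kept only protein-coding loci, or divided the variance by 3, were chosen only after the result was seen. Of the alternatives for the counts of calls, the additivity count and the correlation, 54 were classed as unmoved and 21 as moved. A count was unmoved when it was within 1.5 times the reported one. The correlation was judged more strictly, by the interval of its reported value, 0.439 to 0.467. Every alternative for the correlation lay outside that interval and was among the 21, with its sign kept. By the rule for counts, only Spearman's rho of 0.274 would have been among them. Recentred folds kept the same calls by construction, so their counts could not move. Several other alternatives only took a part of the deposited calls. A reversal was looked for in the correlation alone and not in the counts.

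Normal p-values from the test statistics called 121 loci for fengycin against control (406 as deposited), 106 for surfactin against control (362), 156 for the combined treatment against control (761), 137 for fengycin against surfactin (485), 82 for the combined treatment against fengycin (234) and 194 against surfactin (723). These p-values cannot call loci at FPKM 0, which have no statistic, and at most loci are larger than the deposited ones (97.0% of 12991 loci for fengycin against control). A minimum change of 2-fold left 163, 387 and 376 loci for surfactin against control, combined against control and combined against surfactin, by fewer loci allowed. A q of 0.01 left 225 for surfactin against control.

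The combined treatment against fengycin depended most on the loci kept: 153 calls with a larger FPKM of at least 5, 67 without loci at FPKM 0, 109 over protein-coding loci and 48 over those above 0 in both groups. For fengycin against control, the last restriction left 269. In each case a part of the deposited calls was taken, with no new test.

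Departures from additivity numbered 104 with the variance divided by 3 and 7 over protein-coding loci alone. The correlation of fengycin and surfactin effects, 0.453, became 0.570 at a mean FPKM of at least 5, 0.274 as Spearman's rho, 0.503 with a pseudocount of 1 and 0.335 over protein-coding loci with a mean FPKM of at least 5; the cause was not tested. Of 24 alternatives for named genes, 23 stayed within the SE, and FVEG_17658 with surfactin moved to -6.85 with the pseudocount, as adding 1 FPKM to a low value does. The largest shift was that of FVEG_17658 with the combined treatment, from -8.88 to -7.40, within its wide SE of 2.10.

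No paired analysis was possible because the authors' deposited table holds values per group only. For the same reason the replicate block, leaving out each sample and other splits of the samples were not run, so no result here was tested against the loss of a single library. The gene list tests were not run because the gene table used named no products. Depth per sample is unknown, and what it limits could not be worked out.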

Other observations

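The main effects, the tests of neighbours and chromosome ends and all tests of explanations in this part were chosen only after the result was seen.

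Averaged over both backgrounds, fengycin raised 130 and lowered 6 of 11593 protein-coding loci, and surfactin raised 19 and lowered 2 (z test, Benjamini-Hochberg). These averages include loci that departed from additivity: 1 of the 130, 4 of the 19 and 1 of the 2. FVEG_02219 is counted both as raised by fengycin and as lowered by surfactin, although surfactin alone left it at 8.86 FPKM against 7.71 in control in the authors' deposited table. FVEG_09758 on chromosome 1 was at 63.4 FPKM in control, 459 in fengycin, 72.5 in surfactin and 517 in the combined treatment in the authors' deposited table, a fengycin effect of 2.84 (SE 0.20) on the log2 scale. FVEG_11731 on chromosome 7 had a fengycin effect of 3.73 (SE 0.29) and FVEG_12324 on chromosome 4 of 3.29 (SE 0.26). FVEG_10660 on chromosome 11 fell with fengycin (-1.38, SE 0.31). For surfactin, FVEG_08011 on chromosome 3 went from 426 to 889 FPKM without fengycin and from 465 to 830 FPKM with it in the authors' deposited table, an effect of 0.95 (SE 0.18). FVEG_13866 had a surfactin effect of 2.26 (SE 0.23). These genes were chosen after their values were seen.

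Called protein-coding genes lay beside each other more often than permuted calls. Genes higher with fengycin than with surfactin formed 33 neighbouring pairs against 6.43 expected, and genes lower with surfactin than in control formed 12 against 0.61. Each of these had a one-sided permutation p of 0.000999, the smallest that the permutations can give (Benjamini-Hochberg adjusted p = 0.0012 over 12 tests). Pairs in the combined treatment against fengycin did not exceed permuted calls by this test, at 0 higher and 2 lower. Loci that overlap each other were not left out: FVEG_12010 and FVEG_12011 on chromosome 4 both span 2780920 to 2785347. How many pairs share reads was not tested, so the excess of pairs is not a count of genes that respond independently. Genes within 300 kb of chromosome ends were also called often: 105 higher and 59 lower in the combined treatment against control, where permutation within FPKM deciles gave 51.8 and 31.6. Within the same 300 kb, genes lower in the combined treatment than in surfactin numbered 34 against 27.3, which did not pass the permutation test (adjusted p = 0.0992), and genes lower than in fengycin numbered 13 against 16.1 (adjusted p = 0.856). For higher calls the excess depended on the distance: within 100 kb they numbered 21 in the combined treatment against control, with 20.0 expected (Fisher's exact test, adjusted p = 1.0), and 11 with fengycin against control, with 11.8 expected. Lower calls within 100 kb passed Fisher's exact test in both the combined treatment against control, at 23 with 12.8 expected, and fengycin against control, at 8 with 2.79 expected (adjusted p = 0.037 for both). The other 4 comparisons did not pass for lower calls, with adjusted p from 0.271 to 0.984. Both tests of chromosome ends treat loci as independent, although calls lay beside each other. Their p-values do not allow for this clustering and are too small to that extent.

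The combined treatment was called different from fengycin at fewer loci than from surfactin. Part of this contrast may come from the deposited p-values, which were less strict against surfactin at the same statistic: normal p-values called 82 and 194 loci. A larger spread of the fengycin libraries as the whole cause is argued against by the fold changes themselves: their median absolute deviation was 0.149 against fengycin and 0.201 against surfactin, a difference of -0.0571 to -0.0454 by bootstrap over loci. A library difference, which may or may not lie behind the rRNA pattern, was also considered. Shared alike by fengycin and surfactin, it would move the combined treatment away from both. It therefore does not by itself predict fewer calls against fengycin, and the correlations do not test it as a cause of that contrast. Such a difference would make the fengycin effects without and with surfactin correlate negatively. As the whole source of the fengycin effects it is argued against by correlations above 0: 0.475 across protein-coding loci, 0.131 (95% interval 0.114 to 0.149) across all loci and 0.0978 (0.0768 to 0.119) across all with a mean FPKM of at least 5. Loci are not independent replicates, and the lower values with all loci kept leave a partial contribution to those effects open. Fengycin may act in the combination as it does alone while surfactin adds less, but the values do not decide it. Surfactin effects without and with fengycin correlated at 0.147 over protein-coding loci, -0.094 over all loci and -0.245 at a mean FPKM of at least 5. The hypothesis also stays open because the labels do not give the dose of each lipopeptide in the combination.

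Very short loci without a gene carried the highest FPKM values. Of 110 loci of at most 40 bp, 109 were 36 bp long. Length correction of small numbers of fragments may account for their values: their 111 values above 0 took only 51 distinct levels. Steps were sought as a smallest value divided by 10, up to 3 per group, 10 in all. Of the 101 values that defined no step, 100% were whole multiples of a step within 0.1%, against at most 27.3% in 1000 random draws put through the same search. Repeated levels were each counted, and the random draws held no repeats, so part of this contrast comes from the repeats. Surfactin, with 3 values and 3 steps, added nothing to this test. Transcription under a single treatment was not tested against chance and stays open: 109 of the 110 loci were above 0 in 1 group alone. In the combined treatment against fengycin, 18 of these loci were called lower and 2 higher.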
